A study of Mus musculus with 4 samples.

How the data were processed

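Whole retinas of Fezf2 knockout mice and control littermates, on the background the labels give as C57/BL/6J, were sequenced at postnatal days 7 and 14, with 1 library per genotype and age. Per the labels' protocols, total RNA was extracted with the RNeasy Plus Micro Kit and reverse-transcribed with random primers, and cDNA of about 200 bp was amplified and read as 36-base single ends. The steps named there include no strand marking and no selection of polyadenylated RNA, so reads from overlapping or antisense genes cannot be told apart. The deposited values are FPKM, fragments scaled by transcript length and by the mapped fragments of the library, for each gene, made by the authors with CASAVA 1.8.2, TopHat2 2.0.8b and Cufflinks 2.1.1 against the mm9 build, per the submitters' processing notes. The gene annotation and the options of these tools are not given in the sources used here. Each deposited FPKM has a lower and an upper bound and a status, per the file headers.

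Every library listed 23021 loci under 22558 symbols, of which 251 symbols stood at several loci and were summed. Levels marked as failed were listed at 0 (8, 7, 5 and 5 loci in the control P7, KO P7, control P14 and KO P14 libraries), and the 16 symbols affected were left out wherever a failed value would enter. Coordinates are from the files, in mm9 and counted from 1. Cufflinks divides by an effective length, which inflates very short genes, so 735 small RNA genes and loci under 300 bases were tallied separately. They held 10.7%, 9.41%, 9.16% and 7.95% of the summed FPKM of the libraries, in the same order. FPKM exceeded its own upper bound at 2176, 2080, 1809 and 2243 loci, so bounds were compared only with bounds.

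The files hold no counts. If the bounds span 2 standard deviations of a counting error on each side, they imply about 11900000, 11600000, 9300000 and 12400000 fragments. These implied counts were within 0.1 of a whole number for 24.7% to 26.9% of the loci tried, so they give depth only approximately and no count test was run. The median half-width of the bounds was 13.0% to 15.5% of the level for loci at 1 to 10 FPKM and 6.26% to 7.62% above 10 FPKM. Amplified reads without molecular identifiers are not independent molecules, so the bounds cover counting error only.

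Values were compared as log2(FPKM + 1), which understates the change of low genes, and every fold is on that scale. The comparisons were KO against control at P7 and at P14, P14 against P7 in each genotype, and the similarity of the genotype differences between the ages, which share no library. The groups, comparisons, rules, gene lists and most alternatives were fixed before the data were examined. With 1 library per group, genes were counted by a fixed rule of 2-fold at 1 FPKM or more in either library. The number past a rule at both ages was set beside the number for independent lists. Genotype and age were also fitted together over the 4 libraries with limma, on log2(FPKM + 1) of genes at 1 FPKM or more in at least 2 libraries, with a variance trend and Benjamini-Hochberg adjustment. That fit has 1 residual degree of freedom, which is the difference between the genotype differences at the 2 ages, so it leans on a spread shared between genes (5.09 prior degrees of freedom, 10.7 with small RNAs left out).

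Of 33 gene lists for retinal cell types, neighbouring tissues, pathways and technical checks, the median log2 difference of members with a mean of 1 FPKM or more was placed among 10000 random lists of the same size, matched on 20 bins of expression. The central range runs from percentile 2.5 to 97.5. The random lists describe these libraries and are not replicates, since they draw genes independently while genes of a cell type move together. Some lists share genes with others.

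Genes named in the text followed a fixed rule: Fezf2 and Fezf1, and for each genotype comparison the 10 highest and 10 lowest log2 differences at 2 FPKM or more with bounds that did not overlap. The rule added up to 8 genes per direction at least 1.5-fold apart the same way at both ages, up to 4 members per list, all OFF and ON cone bipolar members and the 6 largest age changes per direction in the control. Small RNAs, loci under 300 bases, symbols at several loci and sex-linked genes were left out of the ranked parts.

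The limma step was tested on 20 simulated data sets of 12937 genes with 200 changed genes, for the genotype term. Each change was the same at both ages, and the noise was drawn independently for each gene. Changes that turn with age and genes that move together within a library were not simulated, so the shares below may not hold for these libraries. Of 50 genes changed 1.5-fold a median of 44.5 was recovered (33 to 49), and of 50 changed 2-fold a median of 50. Unchanged genes made up a median of 7.78% of the calls, from 0.546% to 25.7%, against a nominal 5%, so limma calls here can hold more false ones than their threshold implies. The list step was tested on random lists of 18 genes at P7. Of 20 lists with no shift 1 lay outside the central range, as did 17 of 20 with a log2 shift of 0.1 and 20 of 20 with one of 0.2.

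The alternatives were a pseudocount of 0.1 FPKM, scaling by median ratios, rescaling to TPM, no floor or a floor of 5 FPKM, a 1.5-fold rule, bounds that do not overlap, the highest of several loci, leaving out small RNAs, limma with no trend, and each age alone for the lists. Leaving small RNAs out of the limma fit and of the age counts was chosen after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.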

Results

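The role of Fezf2, a zinc-finger transcription factor, in the developing mouse retina was addressed by RNA sequencing of whole retinas from Fezf2 knockout (KO) mice and control littermates. Retinas were taken at postnatal day 7 (P7) and postnatal day 14 (P14), and 1 library was made for each genotype and age, 4 in all. No group therefore had a replicate, and no test was possible between the genotypes at a single age. Each library listed 23021 gene loci under 22558 symbols, with the expression level in FPKM and a lower and an upper bound for each level. The widths of these bounds implied about 11900000 fragments in the control P7 library, 11600000 in the KO P7 library, 9300000 in the control P14 library and 12400000 in the KO P14 library. The bounds cover counting error within a library, not differences between mice or dissections, and a difference is described below as beyond counting error where the bounds of the libraries compared did not overlap. With small RNAs and short loci left out, 1703 of 12672 genes differed in this way between the genotypes at P7 and 2011 of 12816 at P14. A few such genes in a list therefore say little on their own.

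Fezf2 itself was low in both KO libraries. The gene lies on chromosome 14 from base 13174406 to 13178379 of the mm9 build, and its level was 8.32 FPKM in the control and 0.592 FPKM in the KO library at P7 (bounds 7.00 to 8.85 and 0.378 to 0.792). At P14 it was 4.02 FPKM in the control and 0.126 FPKM in the KO library (bounds 3.20 to 4.69 and 0.0494 to 0.214). The KO level was 7.12% of the control level at P7 and 3.14% at P14, log2 differences of -2.55 and -2.16 after adding 1 FPKM to each value. Fezf1, the paralog of Fezf2, stayed under 1 FPKM in all 4 libraries and was lower in the KO library at both ages, at 0.295 against 0.697 FPKM at P7 and 0.396 against 0.972 FPKM at P14.

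At P7, genes of OFF cone bipolar cells, the retinal interneurons that respond to light decrements, were on balance higher in the KO retina. Neto1, an auxiliary subunit of kainate receptors, was at 7.78 FPKM in the KO and 4.01 FPKM in the control library (log2 difference 0.81), and the homeobox gene Irx6 was at 18.5 against 11.6 FPKM (0.63). Nxph1 was at 11.6 against 7.73 FPKM (0.53) and Vsx1, a homeobox gene of cone bipolar cells, at 45.5 against 33.3 FPKM (0.44). Zfhx4 and Lhx3 were also higher beyond counting error (0.39 and 0.32), whereas the kainate receptor gene Grik1 (-0.28) and the protocadherin gene Pcdh10 (-0.27) were lower beyond it. Of the 18 measured genes of this list 11 were higher and 7 lower, and the median log2 difference of 0.08 lay above the central range of -0.08 to 0.07 of 10000 random lists matched on expression.

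The other bipolar lists did not move together at P7. ON cone bipolar genes had a median of 0.10 (percentile 98.98). Of 16 measured members 10 were higher, 3 beyond counting error, and 6 lower, 1 beyond it. Among the higher were Scgn at 33.2 against 25.2 FPKM (0.38) and Gnb3, which is also in the cone photoreceptor list, at 297 against 246 FPKM (0.27). Rod bipolar genes had a median of -0.07 (percentile 1.14), with 13 of 16 lower, 3 of them beyond counting error, and 3 higher, 1 of them beyond it. Among them were Gabrr1, a GABA receptor gene, at 25.1 against 30.5 FPKM (-0.27), and Grm6, the glutamate receptor gene of ON bipolar cells, at 16.4 against 19.9 FPKM (-0.26). Genes of bipolar cells in general had a median of -0.06 (percentile 0.600), with 14 of 19 lower, 4 of them beyond counting error, and 5 higher, 1 of them beyond it. Among them Lrtm1 was at 0.618 against 1.98 FPKM (-0.88). This list shares genes with the rod bipolar list, Grm6 among them.

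Cone genes were higher in the KO retina at P7, with a median of 0.18 (percentile 100). The short-wavelength opsin gene Opn1sw was at 72.9 against 51.0 FPKM (0.51) and the cone phosphodiesterase gene Pde6h at 144 against 109 FPKM (0.40). Rod genes had a median of 0.00, which became -0.02 on a TPM scale, with 12 members higher and 12 lower. The random lists matched to them centred on 0.07 (central range 0.03 to 0.10), so percentile 0.130 goes with a median near 0. Guca1a, which is also in the cone list, was higher (0.44) and Guca1b lower (-0.46). All 11 measured horizontal cell genes were higher, 4 of them beyond counting error (median 0.16, percentile 99.9). Among these 4 were Lhx1 at 7.54 against 5.20 FPKM (0.46) and Onecut2 at 2.42 against 1.72 FPKM (0.33). Synaptic genes had a median of -0.01 (percentile 0.920), ribosomal protein genes 0.11 (percentile 99.02) and replication histone genes 0.19 (percentile 99.9). The matched random lists centred on 0.05 for synaptic and 0.07 for ribosomal protein genes. The histone median became 0.37 with a pseudocount of 0.1 FPKM, and 0 of the 10 histone genes differed beyond counting error.

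The genes furthest apart at P7 were of other kinds. Higher in the KO library were Optc, which encodes the vitreous proteoglycan opticin (19.5 against 3.22 FPKM, log2 difference 2.28), and the lens crystallin gene Cryaa (4.43 against 0.122 FPKM, 2.27). Crhbp (1.21), Spp1 (1.13) and the gap junction gene Gja1 (1.06) were higher as well. Lists of neighbouring tissue and blood had higher medians in this library too, 0.13 for the retinal pigment epithelium (percentile 99.9), 0.27 for 5 measured lens genes (percentile 99.8), 0.32 for 7 of ciliary body, iris and cornea (percentile 100) and 0.22 for 5 erythroid genes (percentile 99.9). Beyond counting error were 3 of 15 pigment epithelium, 1 of 5 lens, 4 of 7 ciliary, iris and cornea and 1 of 5 erythroid genes, the last being Hba-a2, whose value is uncertain because of its copy Hba-a1. The median of the ciliary, iris and cornea list was 0.01 with no floor on expression, and that of the lens list was 1.41 on a TPM scale. Lower in the KO library were the noncoding RNAs A930011O12Rik (12.2 against 58.8 FPKM, -2.18), Meg3 (11.4 against 37.2 FPKM, -1.62) and Snhg11 (4.08 against 13.2 FPKM, -1.48), and Gsg1 (14.0 against 39.0 FPKM, -1.42), U90926 (-1.75) and Cdk5rap1 (-1.58). Amd1 (-2.82), Rps27 (-1.98), Rpl26 (1.84) and Atp6v0c-ps2 (-1.60) also stood out, but they share sequence with related copies or pseudogenes, so their values are uncertain.

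By the rule of a 2-fold difference, 54 of 12832 genes were higher and 98 lower in the KO library at P7, and the higher count became 83 with a pseudocount of 0.1 FPKM and 84 on a TPM scale. Small RNA genes and loci under 300 bases made up 39 and 75 of these, and without them 15 genes were higher and 23 lower, 15 and 20 of them beyond counting error. Of 12672 such genes 98.98% differed by less than 1.5-fold, and the levels of the P7 libraries correlated across genes with a Pearson coefficient of 0.994. Medians within the central range of the random lists at P7 were found for amacrine (-0.05), ganglion cell (0.07), Mueller glia (0.05), progenitor and cell cycle (-0.01), Notch pathway (0.04), Fezf2-related deep-layer cortical (0.04) and retinal transcription factor genes (0.03). They were also found for muscle (-0.06), microglia (0.02), endothelium and pericyte (0.01), astrocyte (0.09), reactive glia (0.05), immediate early (-0.02), interferon (-0.03), p53 and apoptosis (0.07), oxidative phosphorylation (0.08) and housekeeping genes (0.03). In all, 6 of 33 lists lay below and 10 above the central range, against 1.65 outside it by chance for lists of unrelated genes.

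At P14, genes of OFF cone bipolar cells were on balance lower in the KO retina. Grik1 was at 14.6 FPKM in the KO and 27.8 FPKM in the control library (log2 difference -0.89), and Tacr3, the neurokinin 3 receptor gene, was at 6.89 against 11.6 FPKM (-0.67). Nxph1 was at 4.58 against 7.09 FPKM (-0.54), Bhlhe22 at 13.9 against 19.3 FPKM (-0.45), Pcdh17 at 3.10 against 4.51 FPKM (-0.43) and Pcdh10 at 13.2 against 17.5 FPKM (-0.38). These 6 genes were lower beyond counting error, and 0 of the 18 measured members were higher beyond it. Among all genes without small RNAs and short loci, 2011 of 12816 differed beyond it at P14 in either direction. In total 15 of 18 were lower, with a median of -0.13 (percentile 0.280), or -0.26 on a TPM scale. Vsx1 (-0.08), Neto1 (-0.22), Irx6 (0.14), Lhx3 (-0.19) and Zfhx4 (-0.02), all higher at P7, differed by less than counting error at P14.

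**Figure D1:**
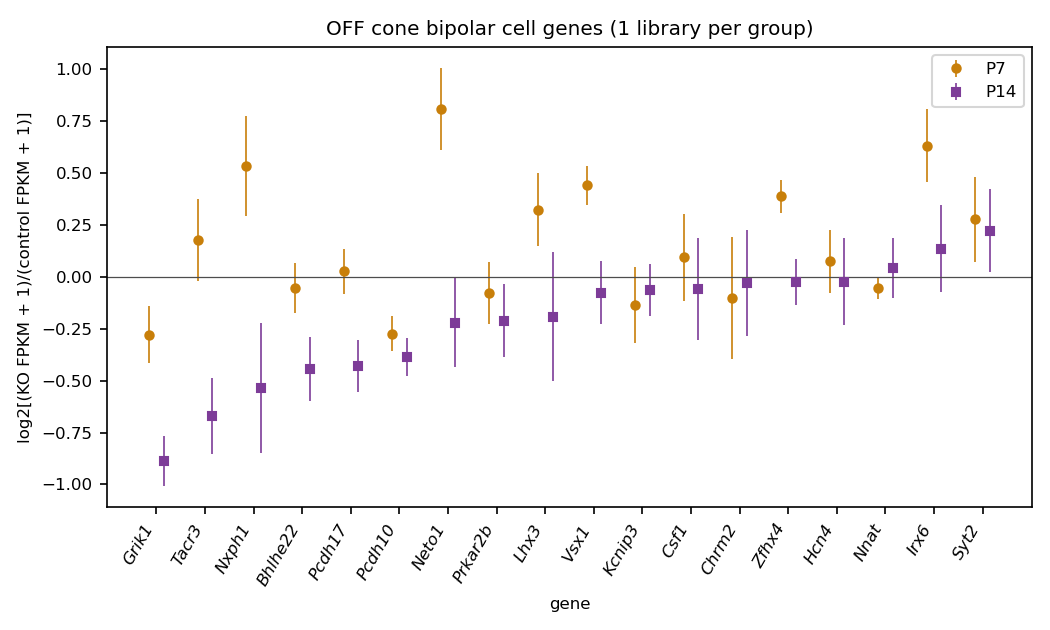
Log2 ratio of KO to control FPKM, after adding 1 to each, for the 18 measured OFF cone bipolar genes at P7 (circles) and P14 (squares), with 1 library per group. Bars combine the relative half-widths of the deposited bounds of both libraries and cover counting error only. At P14 Grik1 stands lowest at -0.89, and at P7 Neto1 stands highest at 0.81.

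Bipolar genes in general were lower at P14 as well, with 14 of 19 lower, 10 of them beyond counting error, 5 higher, 2 of them beyond it, and a median of -0.20 (percentile 0). Cabp5, a calcium-binding protein gene of bipolar cells, was at 49.4 against 67.7 FPKM (-0.45), Trpm1, the transduction channel gene of ON bipolar cells, at 32.8 against 38.7 FPKM (-0.23) and Grm6 at 23.4 against 28.2 FPKM (-0.26). Rod bipolar genes went both ways, 7 higher and 9 lower, 2 and 3 beyond counting error, with a median of -0.08 (percentile 1.77) and a mean of -0.02. The rod bipolar and general bipolar lists share genes of ON bipolar cells, Grm6 and Trpm1 among them, so their medians are not independent. ON cone bipolar genes had a median of 0.02 (percentile 64.8), with Scgn at 47.2 against 58.1 FPKM (-0.29). The synaptic list had a median of -0.02, just below the central range, which was centred on 0.06. In it the photoreceptor and bipolar calcium channel gene Cacna1f was at 11.5 against 18.6 FPKM (-0.64). Among cone genes the arrestin gene Arr3 was at 26.2 against 40.9 FPKM (-0.62), while the list's median was 0.06.

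Horizontal cell genes (median 0.16, percentile 99.2) and ganglion cell genes (median 0.16, percentile 99.9) were higher in the KO retina at P14. Examples were Adra2a at 11.1 against 8.25 FPKM (0.39), Sept4 at 153 against 123 FPKM (0.31), the ganglion cell transcription factor gene Isl2 at 5.47 against 3.69 FPKM (0.46) and Tppp3 at 159 against 116 FPKM (0.45). Genes of the Notch pathway had a median of 0.09 (percentile 98.9), with 2 of 21 higher and 0 lower beyond counting error. Genes of p53 and apoptosis had one of 0.11 (percentile 97.9), with 3 of 12 higher and 2 lower beyond it. Ribosomal protein genes had a median of 0.16 (percentile 99.3), where the matched random lists centred on 0.08. Replication histone genes had one of 0.16 (percentile 99.6), with 0 higher and 1 lower beyond counting error. The proapoptotic gene Bbc3 was at 4.38 against 1.73 FPKM (0.98).

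Immediate early genes, which respond quickly to activity and handling, and genes of reactive glia were higher in the KO retina at P14. Egr1 was at 18.9 against 5.15 FPKM (log2 difference 1.69), the phosphatase gene Dusp1 at 21.9 against 9.83 FPKM (1.08), Fos at 20.9 against 9.94 FPKM and Nr4a1 at 16.8 against 8.17 FPKM (0.96). Of 11 measured immediate early genes 10 were higher, 8 beyond counting error, and the median was 0.64 (percentile 100), or 0.41 on a TPM scale. Gfap, the intermediate filament gene of reactive Mueller glia and astrocytes, was at 20.6 against 9.32 FPKM (1.06), the metallothionein gene Mt1 at 231 against 141 FPKM (0.71) and Cebpd at 6.06 against 3.53 FPKM (0.64). The reactive glia list had 8 of 12 members higher, 4 beyond counting error, and 4 lower, 2 beyond it, with a median of 0.32 (percentile 100), or 0.12 with no floor and 0.67 with a floor of 5 FPKM.

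Genes of the pigment epithelium and of blood, and some lens, vitreous and matrix genes, were lower in the KO library at P14. Optc was at 4.17 against 39.1 FPKM (log2 difference -2.96), Cryaa at 0.0779 against 4.63 FPKM (-2.38), and the matrix genes Fbln1 and Mfap4 at 0.552 against 5.37 FPKM (-2.04) and 0.636 against 5.43 FPKM (-1.97). Pigment epithelium genes had a median of -0.33 (percentile 0), with 14 of 15 lower, including the melanin enzyme genes Dct (11.9 against 19.6 FPKM, -0.68) and Tyr (0.896 against 1.96 FPKM, -0.65). All 5 measured erythroid genes were lower (median -1.74, percentile 0, or -1.002 with no floor), with Hba-a1 at 247 against 826 FPKM and Hbb-b2 at 49.0 against 178 FPKM, copies of near-identical genes whose single values are uncertain. Microglia genes had a median of -0.16 (percentile 0.780), with 12 of 15 lower, 1 beyond counting error, and 3 higher, 0 beyond it.

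By the 2-fold rule 62 of 12963 genes were higher and 91 lower in the KO library at P14, and the lower count became 153 with a pseudocount of 0.1 FPKM and 143 on a TPM scale. Without 55 and 59 small RNA genes and short loci, 7 were higher and 32 lower, 7 and 30 of them beyond counting error, and 98.5% of 12816 genes differed by less than 1.5-fold. The other genes furthest apart were Snhg11 (6.31 against 27.4 FPKM, -1.96), Meg3 (8.50 against 31.5 FPKM, -1.78), Otor (-1.73) and Wfdc2 (-1.57), all lower, and 8430408G22Rik (1.42), Rprml (1.20) and Gdf1 (1.03), all higher. Rps27 (2.098), uncertain as above, was higher. The median lay within the central range of the random lists for rod (0.10), amacrine (0.05), Mueller glia (0.04), progenitor and cell cycle (0.06), deep-layer cortical (0.04), lens (0.10), ciliary body, iris and cornea (-0.11) and retinal transcription factor genes (0.03). The lens median turned to -0.86 on a TPM scale and -0.18 with no floor, and that of ciliary body, iris and cornea to 0.24 with a floor of 5 FPKM. The median also lay within it for muscle (-0.02), endothelium and pericyte (0.01), astrocyte (-0.004), interferon (0.03), oxidative phosphorylation (0.11) and housekeeping genes (0.01). Of the 33 lists 9 lay below the central range and 8 above it.

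**Figure D2:**
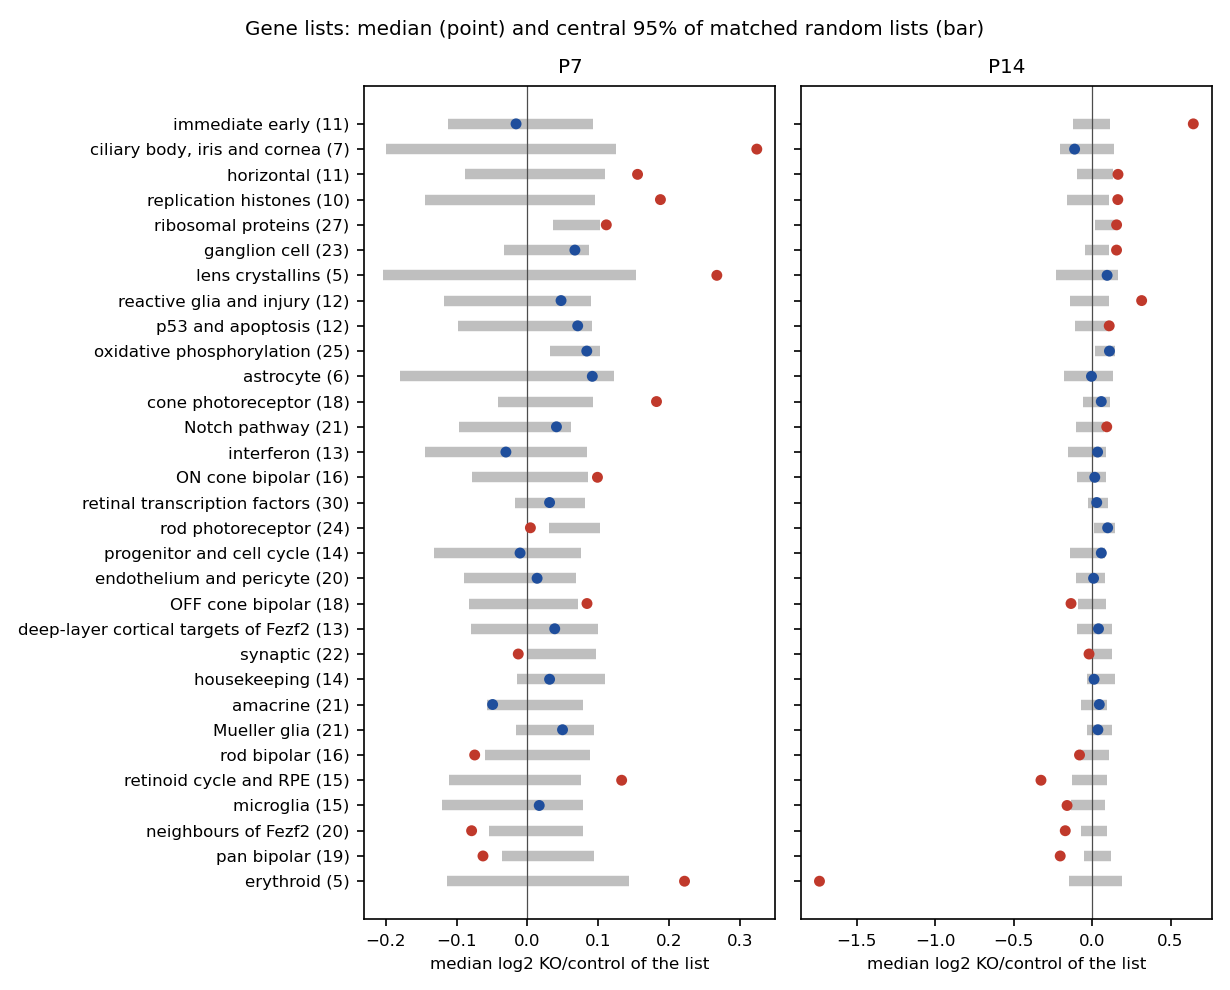
Median log2 ratio of KO to control FPKM for 31 gene lists with 5 or more measured members, at P7 (left) and P14 (right, on a wider axis), with the number of measured genes in parentheses. Grey bars span the central 95% of matched random lists, and red points lie outside them. Immediate early genes stand at 0.64 and erythroid genes at -1.74 at P14.

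A set of RNAs was lower in the KO libraries at both ages. With small RNAs and short loci left out, 18 genes were at least 1.5-fold lower at both ages, against 0.567 for independent lists, and 0 were at least 1.5-fold higher at both. Besides Fezf2 they included the noncoding RNAs A930011O12Rik, Meg3, Snhg11 and Miat, and Leng8, Gsg1 and 6720401G13Rik. Leng8 was at 9.005 against 25.2 FPKM at P7 and 7.74 against 21.1 FPKM at P14, and Miat at 4.25 against 11.3 FPKM and 0.948 against 2.59 FPKM. Another 12 genes were at least 1.5-fold higher at P7 and lower at P14, against 0.2996 for independent lists, and 3 were lower at P7 and higher at P14, against 0.298. Across 12226 genes, which are not independent replicates, the log2 differences at the ages correlated with a Pearson coefficient of 0.07 and a Spearman coefficient of 0.15.

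A limma fit over the 4 libraries, with genotype and age as additive terms, called 31 genes lower and 0 higher in the KO retina at an adjusted p below 0.05 when small RNAs and short loci were left out, a choice made after the data were seen, with 1179 genes at an unadjusted p below 0.05. The fit over all genes called 34, 7 higher and 27 lower. Of these 34, 24 were small RNA genes or short loci, and 10 genes were called by both fits. In the fit without small RNAs, Fezf2 had a log2 difference of -2.35 (SE 0.126, limma adjusted p = 2.84e-06), Meg3 one of -1.70 (SE 0.0897, limma adjusted p = 2.84e-06) and Leng8 one of -1.36 (SE 0.0914, limma adjusted p = 2.38e-05). Among the calls picked out after their values were seen were the splicing factor genes Snrnp70 (-0.54, limma adjusted p = 0.0134) and Luc7l3 (-0.53, limma adjusted p = 0.0333), the photoreceptor cilium gene Rpgrip1 (-0.69, limma adjusted p = 0.0134) and the glycine receptor gene Glra1 (-0.69, limma adjusted p = 0.0396). None of these last 4 genes was called in the fit over all genes. The X-inactivation RNA Xist was at 15.6 against 27.5 FPKM at P7 and 15.6 against 24.9 FPKM at P14, while 4 Y-linked genes summed to 0.389 and 0.403 FPKM at P7 and 0.181 and 0.148 FPKM at P14, the KO library first in each case; the sex of the mice is not given in the labels. Genes near Fezf2 on chromosome 14 had medians of -0.08 at P7 (percentile 0.520) and -0.17 at P14 (percentile 0), with 14 of 20 lower at P14, 7 beyond counting error, and 6 higher, 1 beyond it. At P14 Ptprg was at 3.24 against 5.38 FPKM and Cadps at 42.4 against 57.3 FPKM, while Fhit was at 7.29 against 3.78 FPKM (0.79). The fit has 1 residual degree of freedom, and with no floor on expression it called 0 genes, Fezf2 included, with 1285 at an unadjusted p below 0.05; over the alternatives that tested Fezf2 its limma adjusted p ran from 2.84e-06 to 0.811, and with a floor of 5 FPKM it was not tested.

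**Figure D3:**
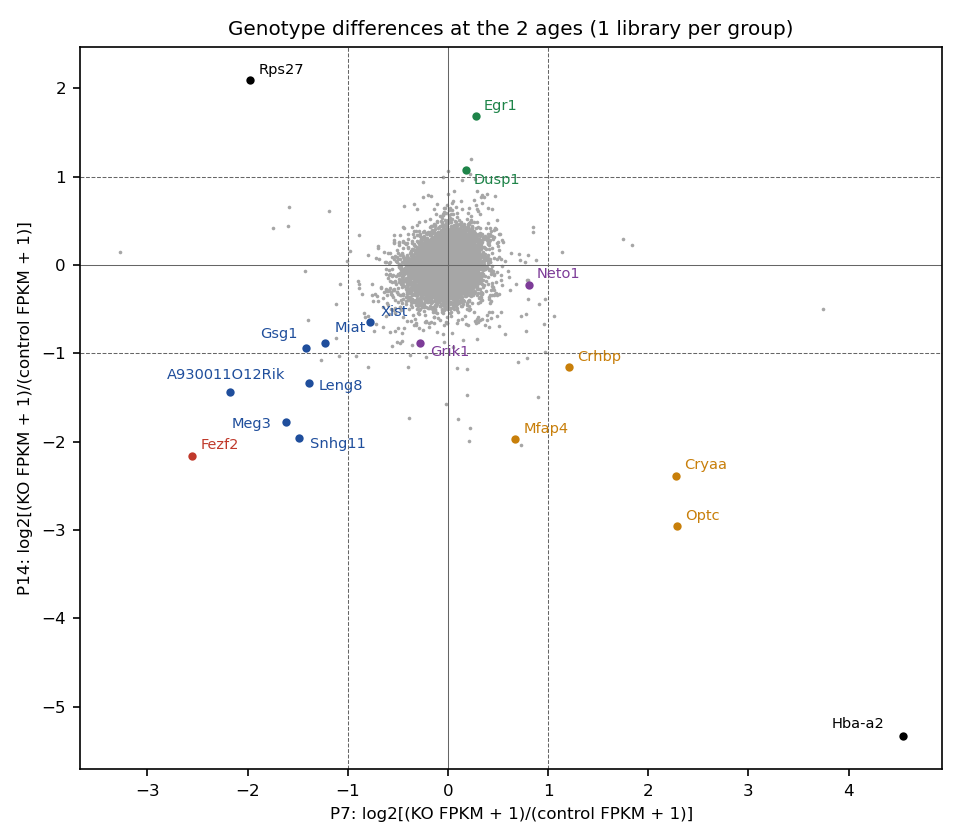
Log2 ratio of KO to control FPKM, after adding 1 to each, at P7 (horizontal axis) and P14 (vertical axis) for genes at 1 FPKM or more in either library at each age, small RNAs and short loci left out. Dashed lines mark a 2-fold difference. Fezf2 (red) stands at -2.55 and -2.16 near other RNAs lower at both ages, noncoding and protein-coding (blue). Optc stands at 2.28 and -2.96 among genes higher at P7 and lower at P14 (orange), and Egr1 (green) at 0.28 and 1.69.

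In the control retina, photoreceptor, rod bipolar and general bipolar genes were on balance higher at P14 than at P7, and progenitor genes lower. Guca1b, a guanylate cyclase activator of rods, was at 7.09 FPKM at P7 and 820 FPKM at P14, the potassium channel gene Kcnj14 at 2.64 and 227 FPKM, the rod transducin gene Gnat1 at 130 and 4979 FPKM and the middle-wavelength opsin gene Opn1mw at 3.70 and 149 FPKM. Fabp7 was at 76.8 FPKM at P7 and 2.56 FPKM at P14, Nnat at 538 and 46.1 FPKM and the transcription factor gene Sox4 at 112 and 9.25 FPKM. The median log2 difference was 1.41 for rod, 1.07 for general bipolar, 1.04 for rod bipolar 0.85 for cone and 0.63 for ON cone bipolar genes, and -0.81 for progenitor and cell cycle, -1.003 for Notch pathway and -0.74 for retinal transcription factor genes. OFF cone bipolar genes had a median of -0.28 (percentile 18.4, within the central range), with 12 of 18 lower at P14, 9 beyond counting error, and 6 higher, 5 beyond it. In the KO retina the same genes had values of 899 FPKM (Guca1b), 5236 FPKM (Gnat1), 4.199 FPKM (Fabp7) and 10.4 FPKM (Sox4) at P14.

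By the 2-fold rule 971 genes were higher and 989 lower at P14 in the control retina, and 1058 and 1085 in the KO retina. Scaling by median ratios, which moved the median of all genes by 0.10 in both genotypes on the log2 scale, gave 1193 higher and 772 lower in the control and 1264 and 868 in the KO retina. Rescaling to TPM tipped the split the other way, to 1206 higher and 1568 lower in the control and 1258 and 1737 in the KO retina. The limma fit called 8858 of 13057 genes for age, 3775 higher and 5083 lower at P14, and 0 with no floor on expression, where 8958 had an unadjusted p below 0.05.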

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

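The test of counting error below was chosen after the result was seen. The ciliary body list was written after Optc, Mfap4 and Cryaa had been seen and before the values of its own genes were.

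Several genes differed in opposite directions at the ages, each by at least 2-fold at both, and the difference between the ages was not tested. The log2 difference at P7 minus that at P14 was 5.24 for Optc, 4.66 for Cryaa, 2.37 for Crhbp, 9.88 for Hba-a2 and -4.07 for Rps27. Hba-a2 has a near-identical copy in Hba-a1, and Rps27 has processed pseudogenes, so fragments could be assigned to the wrong copy in single libraries. Of the lists, 3 lay outside the random range in opposite directions, also untested. The P7 minus P14 difference of the medians was 0.22 for OFF cone bipolar genes, 0.46 for pigment epithelium genes and 1.96 for erythroid genes. Whether the OFF cone bipolar difference belongs to the genotype or to the single libraries was not tested.

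The pattern of genes higher in the KO library at P7 and lower at P14 held 12 genes. Counting error as the whole cause is argued against: 11 of the 12 had bounds that did not overlap at either age, where counting error as wide as the bounds would give 0.071 such genes among all 12226 measured. Different amounts of ciliary body tissue in the libraries may account for part of it. A ciliary body list was used that shares no gene with the pattern or the other lists. Its 9 measured genes had medians of 0.26 at P7 and -0.29 at P14, a difference of 0.55, and both medians lay outside the random lists. Its most abundant members, named for their levels after these were seen, did not all move: at P7 Tgfb2 was at 46.4 against 45.7 FPKM, Col2a1 at 36.5 against 40.5 FPKM and Col9a1 at 49.2 against 36.8 FPKM, and at P14 Aqp1 was at 51.0 against 49.5 FPKM. The pattern also held the lens crystallin genes Cryaa, Cryba1 and Cryba4 and the globin gene Hba-a2. Pigment epithelium genes (medians 0.13 at P7 and -0.33 at P14) and erythroid genes (0.22 and -1.74) turned the same way. The ciliary body list thus cannot tell this tissue from other neighbouring tissue or blood. An effect of the genotype that turns with age stays open, since each age has 1 library per genotype.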

How the results depend on the processing

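Across all alternatives, 786 values for counts, correlations, list medians and Fezf2 moved little, 77 moved further and 9 of results outside the random range turned. In all 51 of these values lay on the other side of 0 from the reported one, 33 of them among those that moved little. Of the values for other named genes 1008 moved little and 36 moved further, and 8, all among those that moved little, changed sign. "Moved little" means within 1.5 times for a count, within the half-width of the random range for a list, and within counting error for a gene. Leaving out 1 library leaves the limma fit no residual degree of freedom, so it gave no test. A pseudocount of 0.1 FPKM gave 83 genes higher at P7 and 153 lower at P14, log2 differences of -3.60 and -4.19 for Fezf2, and a median of 0.37 for replication histones at P7. Rescaling to TPM gave 84 higher at P7, 143 lower at P14, 1568 and 1737 lower with age in control and KO, and -3.17 and -3.06 for Fezf2. It also gave medians of -0.26 (P14) and -0.11 (both ages) for OFF cone bipolar, -0.0201 for rod genes at P7, 1.41 and -0.86 for lens genes at P7 and P14, -0.14 over both ages for ciliary body, iris and cornea, and 0.41 for immediate early genes at P14. TPM values are larger than FPKM here, so the pseudocount and the floor weigh less by construction. With no floor limma called 0 genes for genotype and 0 for age, and 3727 genes at 0 in all 4 libraries entered, with 0.748 prior degrees of freedom. The list medians then were -0.066 (OFF cone bipolar, both ages), 0.70 and -0.18 (lens, P7 and P14), 0.0107 and 0.000239 (ciliary body, iris and cornea, P7 and both ages), -1.002 and -0.34 (erythroid, P14 and both ages), 0.12 (reactive glia, P14), 0.42 and 0.19 (immediate early, P14 and both ages) and 0 for sex-linked genes. A floor of 5 FPKM, which leaves fewer members, gave 0.27 (cone, P7), -0.0705 (amacrine, P14), 0.24 (ciliary body, iris and cornea, P14), -0.67 (erythroid, both ages), 0.67 and 0.27 (reactive glia, P14 and both ages), 0.83 and 0.45 (immediate early, P14 and both ages) and 0.13 (interferon, P7). The 1.5-fold rule gave 93 higher and 161 lower at P7, 114 and 195 at P14, 2201 and 2827 with age in control, 2336 and 2881 in KO, and 41 lower at both ages. Requiring bounds that did not overlap left 16 and 29 at P7, 9 and 34 at P14, and 0 higher and 7 lower at both ages. Leaving small RNAs out left 15 and 23, 7 and 32, and 0 and 7. With each age alone, the median of the mean over ages ranged from -0.13 to 0.0841 for OFF cone bipolar, -0.20 to -0.0627 for general bipolar, 0.00421 to 0.0989 for rod, 0.0582 to 0.18 for cone, -0.0491 to 0.0455 for amacrine and 0.067 to 0.16 for ganglion cell genes. It ranged from 0.0366 to 0.0495 for Mueller glia, against -0.02 for both ages, and from 0.0121 to 0.0313 for housekeeping genes, against -0.01. The ranges were -0.33 to 0.13 for pigment epithelium, 0.10 to 0.27 for lens, -0.11 to 0.32 for ciliary body, iris and cornea, -1.74 to 0.22 for erythroid, -0.16 to 0.0167 for microglia, 0.0474 to 0.32 for reactive glia, -0.016 to 0.64 for immediate early genes and -0.17 to -0.0788 for neighbours of Fezf2. Apart from the constructions named, the cause was not tested. The depth of about 9300000 to 12400000 fragments limits genes near 1 FPKM, whose bounds are widest.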

Other observations

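The tests of the immediate early genes were chosen after the result was seen. The lists, trends and window in the tests of the other patterns were fixed before the values those tests measure were seen, and after the patterns were noticed.

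The RNAs lower in the KO libraries at both ages included the noncoding RNAs Meg3, Miat and Snhg11 beside protein-coding genes such as Leng8 and Gsg1. A general trend with gene length, taken as the span of the locus with its introns, is argued against by its size. Medians of 20 bins of span ran only from -0.0215 to 0.0861. For GC content they ran from -0.0848 to 0.0892, which argues against that trend too. Subtracting bins this close to 0 could move the calls little. The median log2 difference of the 31 genes called by limma was -0.71 before and -0.74 after subtracting the trend with span. With GC content it was -0.74 before and -0.76 after for the 25 genes with a value. Lower recovery of nuclear-retained RNA in the KO libraries may account for part of the pattern. In a list of nuclear-retained and intron-retaining RNAs, 27 genes, none among the calls, had a median of -0.17 over both ages. It lay below the random range of -0.03 to 0.07. The calls, which were selected as lower, had a median of -0.71, so a shift of the list's size alone does not reach theirs. Malat1 was at 11.8 against 17.6 FPKM at P7, while Srsf3, an abundant member named for its level after this was seen, was at 117 against 120 FPKM and not clearly lower. A difference in RNA processing or retention caused by the genotype predicts the same and stays open. For Xist, a different share of female mice was not tested and stays open too. The 4 Y-linked genes summed to 0.389 FPKM in the KO and 0.403 FPKM in the control library at P7, and to 0.181 and 0.148 FPKM at P14. No clear rise thus matched the lower Xist, though sums this far under the floor of 1 FPKM are weak evidence.

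Immediate early genes were higher in the KO library at P14. Counting error is argued against, since of all 11 measured members of the list, fixed beforehand, 8 were higher with bounds that did not overlap and 0 were lower with such bounds. Such bounds are not particular to these genes. They were found at P14 for 2011 of 12816 genes without small RNAs and short loci. Among 24 rod genes, 16 were higher and 4 lower with such bounds, though the rod median lay within the random range. A difference in handling before RNA extraction, such as the time to dissection or light exposure, cannot be told apart from the genotype, because 1 library per genotype at P14 gives the same median of 0.64 under either. At P7 the median of these genes was -0.02.

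Of the 31 genes called lower by limma, 7 lie on chromosome 14, Fezf2 among them, against 1.09 for a random draw from the genes tested. Of these, 4 (Gm10391, Gm10394, D14Ertd449e and Plac9, picked after their values were seen) lie close together. They span bases 26707889 to 26949271, within 20 Mb of Fezf2. A chromosome 14 segment that differs between the KO and control mice was tested as a hypothesis. The 116 genes within 20 Mb of Fezf2 outside the calls had a median absolute log2 difference of 0.0801, at percentile 59.6 of matched random lists. All called genes were left out of this test, the 4 close together included. It therefore could not count them and does not decide the hypothesis. The 20 measured neighbours of Fezf2 in the list fixed beforehand had a median of -0.10 over both ages (percentile 0), with 14 lower and 6 higher, so the hypothesis stays open.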
